A study of Mus musculus with 14 samples.

How the data were processed

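The samples were growing C2C12 myoblasts, harvested at about 40% confluency in medium with 10% serum, and myotubes harvested after 4 days in 2% horse serum, per the labels' protocols. H3K27ac was immunoprecipitated from chromatin digested with micrococcal nuclease to about 85% mononucleosomes, whereas p300, c-Jun and input used chromatin sonicated to an average of 250 bp, per the labels' protocols. The 14 libraries fall into 6 groups by antibody and state, and the replicate numbers are those of the labels. c-Jun and input of myotubes were not analysed here.

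Each deposited file of a library lists aligned reads, 1 per line with chromosome, position and strand, and holds no value per feature. The genome build is mm9, per the submitters' processing notes. The aligner, the mapping filters and the treatment of duplicates are not given in the sources used here, but the deposited files held no more than 1 read per position and strand, so a further removal of duplicates would remove 0 reads. The deposited c-Jun and input files held the same number of reads in each replicate number, 6087173 and 8137453. Reads on unplaced contigs and on the mitochondrial genome were absent from the c-Jun and input files, and reads on unplaced contigs from p300 myotube replicate 3. The deposited peak lists give boundaries only, 1 list per antibody and state. The peak caller, its threshold, the use of input and whether replicates were pooled are not given in the sources used here.

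Reads on chromosomes 1 to 19 and X were used. Each read was moved towards its 3′ end by 0.5 of the distance between the strands, which was estimated by cross-correlation on chromosome 2 between 80 and 300 bp. The distance was 111 bp for H3K27ac, 201 bp for p300 and 229 bp for c-Jun, which was used for input too. The myoblast and myotube lists of an antibody were merged where they overlapped, giving 336118 H3K27ac and 205920 p300 regions, and reads were counted in each. Wider reads of the H3K27ac change used domains, made by joining regions up to 12.5 kb apart.

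A count model had been fixed as the main test for files that hold reads, before the data were examined. The deposited files hold reads, so the use of limma-voom here departs from that plan. The counts made here were tested with limma-voom, with an offset of 0.5, robust empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05. Library sizes were scaled by the trimmed mean of M values, written for this work with 30% of the log ratios and 5% of the mean levels trimmed. Regions needed the equivalent of 10 reads in a median library in as many libraries as the smallest group and 15 reads in all. c-Jun was compared with input on total reads, since scaling on its own peaks would remove a common enrichment. Fold changes are given on the log2 scale as myotubes over myoblasts, and CPM are relative to the scaled library sizes. Only the libraries of the antibody entered each fit, with no covariate.

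The regions named were the 5 largest log2 fold changes in each direction among those past the threshold with replicates that did not overlap and a mean at or above the median of the tested regions. For domains the same rule was applied, after the data had been seen, to those of at least 10 regions. The c-Jun peaks were to be named by the authors' score. The deposited list holds no score, so that the highest fold over input was used, chosen after the data had been seen.

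Regions with a c-Jun peak, by an overlap of at least 1 bp, were tested as a set against the other regions with limma's camera, two-sided, with a preset correlation of 0.01 and with an estimated one, and adjusted over the 2 sets. Overlaps of peak lists were counted at a minimum of 1 bp, with 95% Wilson intervals, and compared with 100 random placements of the same peaks on the same chromosomes beyond the first 3 Mb. The p300 and H3K27ac changes were correlated across p300 regions, with 1000 permutations. Profiles around c-Jun peak centres used bins of 100 bp out to 3 kb.

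On simulated data with 200 changed regions among 20000, drawn with the means and sizes of the real libraries and a dispersion of 0.03, the H3K27ac test recovered 74.2% of the 4-fold, 20.9% of the 2-fold and 0% of the 1.5-fold changes. The p300 test recovered 65.2%, 4.48% and 0% of them. Over 6168 simulated c-Jun peaks the test recovered 40.9% of the 4-fold, 4.48% of the 2-fold and 0% of the 1.5-fold changes. Each simulation gave 1 false call. The dispersion was set by hand and not estimated from the libraries. In the real data 16.1% of the tested H3K27ac regions and 98.8% of the tested c-Jun peaks were called, a larger share than was simulated. The simulated rates therefore do not measure the power or the error of the tests on these data. Peaks were called on the libraries tested, so that regions listed in 1 state alone are selected for a difference, and regions are not independent of their neighbours.

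The alternatives were other scalings (median-ratio size factors, 10 kb bins, total reads and cyclic loess), no filter on low counts, no robust moderation, windows around region centres, reads without the shift, the replicate number as a block, each library left out in turn, and stricter or looser overlaps. Where leaving out a library left 1 in a group, limma-voom assumed that the lone library varied like the other group. Promoters, gene lists, cell type markers and motifs were not analysed here, because the reference used here is of another genome build. Read handling and overlaps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and tests used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (1.17.8).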

Results

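Enhancers of skeletal muscle cells were mapped in C2C12, a mouse myoblast line that proliferates in serum-rich medium and, once serum is withdrawn, leaves the cell cycle and fuses into multinucleated myotubes. Chromatin immunoprecipitation with sequencing (ChIP-seq) was made for H3K27ac, the acetylation of lysine 27 of histone H3 that marks active promoters and enhancers, and for p300, a histone acetyltransferase recruited to enhancers, in growing myoblasts and in myotubes after 96 h of differentiation. c-Jun, a subunit of the AP-1 transcription factor, and input chromatin were sequenced in myoblasts. There were 2 libraries per state for H3K27ac, 3 per state for p300, and 2 each for c-Jun and input. The H3K27ac libraries held 16837938 and 23576737 aligned reads in myoblasts and 23568537 and 24155328 in myotubes. The p300 libraries held 12008246, 12311138 and 12117126 reads in myoblasts and 10703582, 11590572 and 9092235 in myotubes. The c-Jun and the input libraries each held 6087173 and 8137453 reads. Signal is given as CPM, the reads of a region scaled to a library of 1000000 reads. All positions are given in mouse genome build mm9, and regions are named by position, since gene annotation of that build was not used here.

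H3K27ac was compared between myoblasts and myotubes to find regions that gain or lose the mark as muscle cells differentiate. Of 221504 H3K27ac regions with enough reads, 16522 rose and 19102 fell in myotubes. Regions listed as peaks in myotubes alone had a median log2 fold change of 1.41, and 10916 of the 75577 tested rose. Regions listed in myoblasts alone had a median of -1.27, and 4381 of 38955 fell. The lists were called on the libraries tested, so regions of 1 list alone are selected for such a difference. Among the 106972 tested regions of both lists the median was -0.22, and 14033 fell while 5583 rose. When these regions were fitted and scaled on their own, which was added after the data had been seen, the median was 0.12 and the balance turned, with 6665 higher and 5063 lower. The strongest gain by the rule for naming regions lay on chromosome 3 from 53580828 to 53582393, where H3K27ac went from 0.114 ± 0.079 to 9.41 ± 1.41 CPM (SD, n = 2 per state; log2 fold change 6.09, SE 1.09, limma adjusted p = 0.0107). Gains of 5.82, 5.71, 5.68 and 5.62 on the log2 scale were measured on chromosome 12 from 80059111 to 80060513, chromosome 14 from 60339792 to 60340971, chromosome 11 from 66937485 to 66939566 and chromosome 8 from 11667228 to 11669077. These named gains held only 0 to 9 reads per myoblast library, so their sizes and order are imprecise. The gain on chromosome 12 was 3.99 without myoblast replicate 1 and 7.91 without myoblast replicate 2. The strongest loss lay on chromosome 14 from 68701969 to 68703076, where the signal went from 7.52 ± 4.97 to 0.275 ± 0.037 CPM (log2 fold change -4.46, SE 0.90, adjusted p = 0.0155). Losses with log2 fold changes of -4.43, -4.39, -4.13 and -3.99 followed on chromosome 9 from 70268922 to 70269404, chromosome 6 from 42273583 to 42274575, chromosome 10 from 119913123 to 119914488 and chromosome X from 5977175 to 5978151. No region of these 10 overlapped a c-Jun peak.

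The H3K27ac counts come from limma-voom at a false discovery rate of 0.05, and the replicates of the states did not overlap in any changed region. Among all tested regions 71.0% were separated in this way, and 33.3% would be by chance. The calls were made on the same counts and favour separated replicates, so this describes them and is no independent support. The myoblast libraries differed from each other more than the myotube libraries did: 49.997% and 37.4% of their reads lay in myoblast H3K27ac peaks, against 27.7% and 25.8% in myotubes. The number of changed regions was 78816 without myoblast replicate 1 and 146655 without myoblast replicate 2. It was 6553 without myotube replicate 1 and 6189 without myotube replicate 2, of which 79.6% and 73.2% were higher in myotubes, and in each case 6 of the 10 named regions lost their call: the gains on chromosomes 3, 12, 14 and 11 and the losses on chromosomes 9 and X. Higher regions were 46.4% of the calls, 60.5% (17735 higher, 11560 lower) with cyclic loess normalization and 36.6% (16219 higher, 28047 lower) when 10 kb bins set the scaling. The bins moved the median of all regions from 0.08 to -0.15, so that changes are relative to the scaling chosen. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

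Adjacent changed H3K27ac regions up to 12.5 kb apart mostly went the same way. When H3K27ac regions no more than 12.5 kb apart were joined, a step added after the data had been seen, 3202 of 19345 tested domains rose in myotubes and 1784 fell. Among domains of at least 10 regions, the largest gain covered 19.3 kb of chromosome 13 from 83248910 to 83268258, where H3K27ac went from 1.69 ± 0.79 to 27.9 ± 4.86 CPM (SD, n = 2; log2 fold change 4.03, SE 0.39, limma adjusted p = 0.0132). A domain of 41.8 kb with 27 regions on chromosome 3 from 84898157 to 84940000 rose from 7.28 ± 0.50 to 86.2 ± 2.95 CPM. The largest loss covered 22.4 kb of chromosome 11 from 118369970 to 118392386, from 50.3 ± 23.2 to 10.1 ± 0.90 CPM (log2 fold change -2.22, SE 0.40, adjusted p = 0.0225). A domain with 44 regions on chromosome 2 from 92750464 to 92798068 went from 197 ± 33.5 to 48.9 ± 3.57 CPM. A c-Jun peak lay in 83.4% of the 655 lower domains of this size, in 48.0% of the 910 higher ones and in 71.9% of the 4548 not called (lower against higher, odds ratio 5.42, Fisher's exact test, two-sided, p = 1.25e-48), and domains are not independent replicates. Higher domains were 64.2% of the calls, 44.1% (3113 higher, 3952 lower) when 10 kb bins set the scaling and 52.8% (4522 higher, 4042 lower) with the replicate number as a block. The number of changed domains was 916 without myotube replicate 2, 1397 without myotube replicate 1, 12355 without myoblast replicate 1 and 14482 without myoblast replicate 2.

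**Figure D1:**
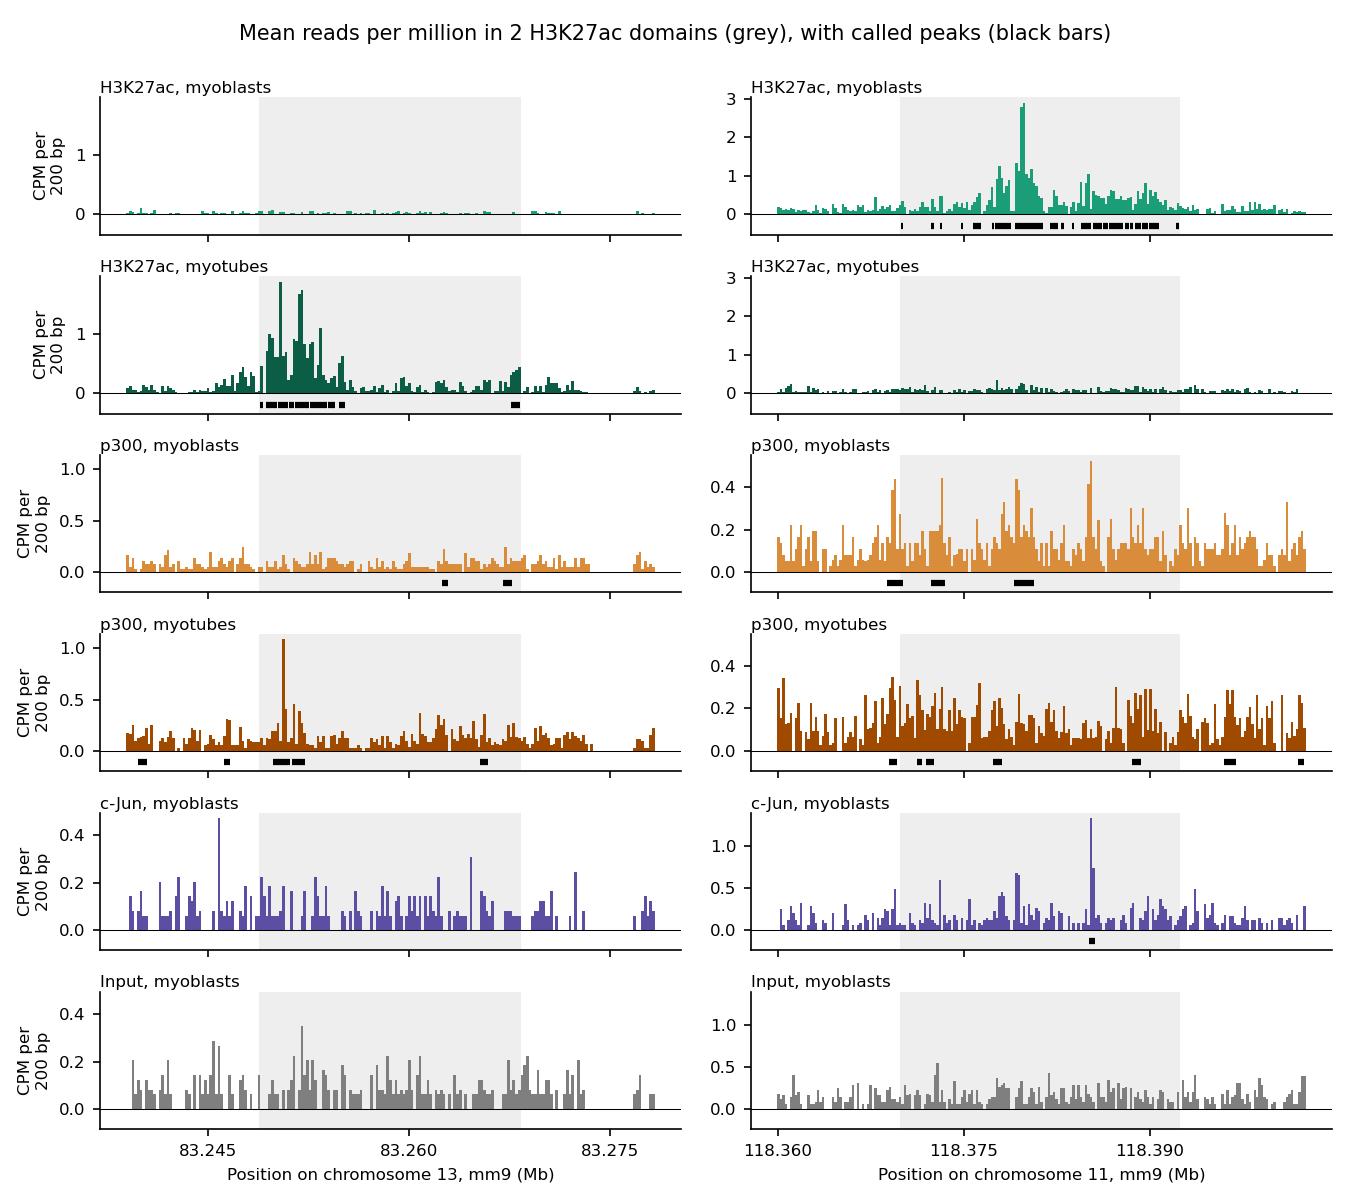
Mean CPM of each group in 200 bp bins across the domain with the largest H3K27ac gain (left, chromosome 13) and the largest loss (right, chromosome 11), both shaded, with 10 kb on each side; black bars are called peaks, and each pair of tracks of an antibody, and c-Jun with input, shares its vertical scale. H3K27ac rose from 1.69 to 27.9 CPM over the left domain and went from 50.3 to 10.1 over the right one, which holds a c-Jun peak.

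p300 was compared in the same way to find regions that gain or lose the coactivator. Of 32872 p300 regions with enough reads, 743 rose and 761 fell in myotubes. Leaving out any 1 myoblast library tilted the balance to losses. There were 555 higher and 1751 lower without replicate 1, 274 and 752 without replicate 2, and 271 and 673 without replicate 3. Each of these fits had unequal groups and a looser filter, with 45355, 43931 and 44322 regions tested. The effects of the libraries, the group sizes and the filter were not told apart. Regions listed in myotubes alone had a median log2 fold change of 0.48 and those listed in myoblasts alone of -0.54. As for H3K27ac, regions of 1 list alone are selected for such a difference. The largest gain lay on chromosome 12 from 110274658 to 110275788, from 0.634 ± 0.547 to 2.88 ± 0.63 CPM (SD, n = 3; log2 fold change 2.82, SE 0.75, limma adjusted p = 0.0211). On chromosome 2 from 180096489 to 180098478 p300 went from 0.751 ± 0.087 to 3.81 ± 0.64 CPM (log2 fold change 2.29, SE 0.33, adjusted p = 4.34e-05). The other named gains had log2 fold changes of 2.41, 2.41 and 2.28 and lay on chromosome 11 from 59136135 to 59136867, chromosome 8 from 32230736 to 32232521 and chromosome 11 from 115772313 to 115773356. The largest loss lay on chromosome 8 from 86904704 to 86906598, from 3.29 ± 0.35 to 0.729 ± 0.539 CPM (log2 fold change -2.38, SE 0.57, adjusted p = 0.00981). On chromosome 10 from 120052665 to 120055371 p300 went from 6.24 ± 1.40 to 1.61 ± 0.31 CPM (log2 fold change -1.92, SE 0.24, adjusted p = 7.46e-06). Losses with log2 fold changes of -2.20, -1.98 and -1.85 lay on chromosome 13 from 23853032 to 23853795, chromosome 1 from 120264866 to 120267097 and chromosome 2 from 5535699 to 5536566. All 5 named p300 losses overlapped a c-Jun peak of myoblasts, and 0 of the 5 named gains did.

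Of the changed p300 regions, 97.4% had replicates of the states that did not overlap, against 28.2% of all tested regions and 10% by chance. Here too the calls were made on the same counts, so the share is no independent support. The lists joined to 205920 p300 regions, most of which held too few reads to be tested. The 1504 changed regions became 2306 without myoblast replicate 1, 944 without myoblast replicate 3, 896 without myotube replicate 1 and 767 without myotube replicate 2. The number was 969 (570 higher, 399 lower) when 10 kb bins set the scaling, and 27 of 5757 tested regions when reads were counted within 250 bp of the region centre. In that setting 8 of the 10 named regions no longer passed the test and the gain on chromosome 11 from 115772313 was not tested. Myotube replicate 3 was the p300 library that held no reads on unplaced contigs, and without it 782 regions rose and 455 fell. Of the named regions, the chromosome 12 gain lost its call without myoblast replicate 1 or 3, the losses on chromosomes 8 and 13 without myotube replicate 1, the loss on chromosome 2 without myotube replicate 2 or 3, and the loss on chromosome 1 with no filter on low counts (adjusted p = 0.275) and with cyclic loess normalization (adjusted p = 0.0642; range over its alternatives 2.33e-11 to 0.275).

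The peak lists themselves were compared to ask how much of each landscape the states share. Of the myoblast H3K27ac peaks, 60.9% (95% Wilson interval 60.6 to 61.1, n = 219797) overlapped a myotube peak, and 48.5% (48.3 to 48.7, n = 273426) of the myotube peaks overlapped a myoblast peak. For p300 the shares were 14.5% (14.3 to 14.7, n = 116838) and 16.3% (16.1 to 16.5, n = 107067). Peaks placed at random gave 10.0% and 8.12% for H3K27ac and 6.34% and 6.98% for p300, and 15.9%, 13.4%, 9.03% and 9.19% when they were placed on input reads, an option added after the data had been seen. In myoblasts 20.5% (20.3 to 20.8) of the p300 peaks lay on H3K27ac peaks and in myotubes 36.8% (36.5 to 37.1), against 8.91% and 11.1% at random and 14.4% and 17.2% on input reads. There was 1 list per antibody and state, so these shares have no replicate error, and the intervals cover counting error only. Most p300 regions of 1 list alone held too few reads to be tested. Of those in myoblasts alone 9808 of 99897 were tested and 4.76% of these were called changed. Of those in myotubes alone 12343 of 89614 were tested and 5.20% were called. The low p300 overlap is therefore no measure of how much p300 binding changed.

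**Figure D2:**
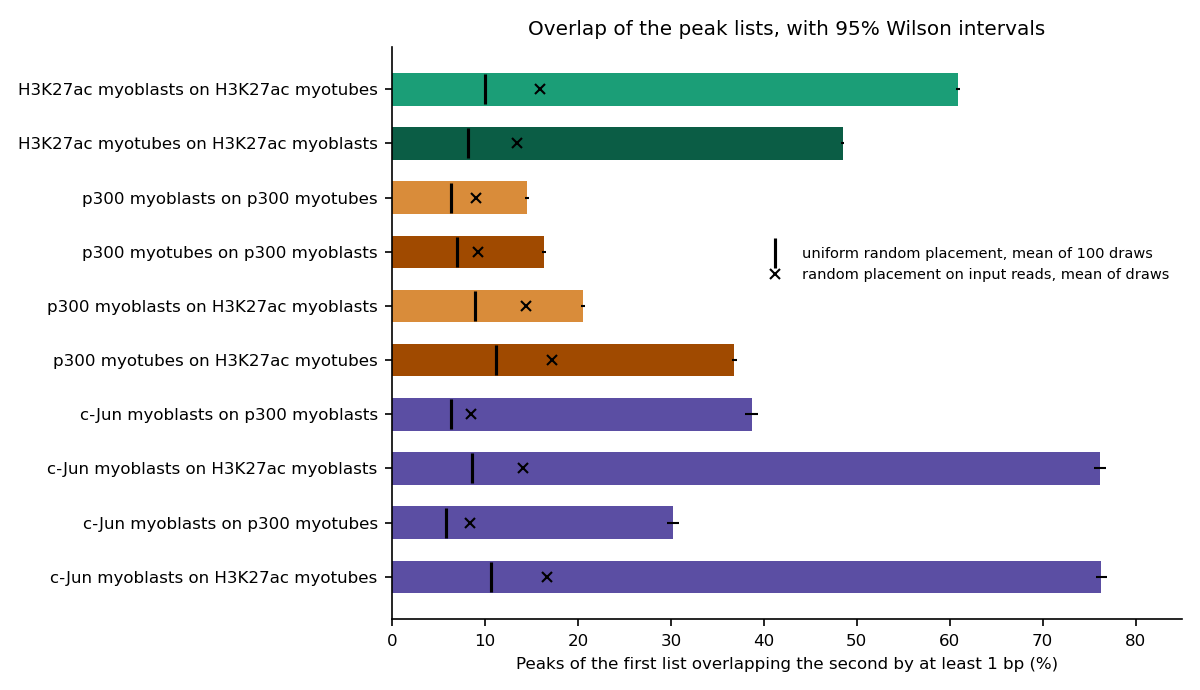
Share of peaks in the first list of each pair that overlapped the second by at least 1 bp, in percent; whiskers are 95% Wilson intervals, vertical ticks the mean of 100 uniform random placements and crosses the mean of 100 placements on input reads. H3K27ac lists shared 60.9% and 48.5% of their peaks between states, p300 lists 14.5% and 16.3%.

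c-Jun was mapped in growing myoblasts, and its peaks were set against their H3K27ac and p300 peaks. Promoters and enhancers were not told apart here. Of 18712 c-Jun peaks, 76.2% (75.5 to 76.8) lay on myoblast H3K27ac peaks and 38.7% (38.0 to 39.4) on myoblast p300 peaks, against 8.60% and 6.35% at random and 14.05% and 8.45% on input reads. On the myotube lists the shares were 76.3% for H3K27ac and 30.2% for p300, so the H3K27ac overlap was not particular to myoblasts. Both marks were present at 6055 c-Jun peaks (32.4%), H3K27ac alone at 8197 (43.8%), p300 alone at 1184 (6.33%) and neither at 3276 (17.5%). Among H3K27ac peaks, 24.8% of those with p300 and 5.27% of those without held a c-Jun peak (odds ratio 5.92, Fisher's exact test, two-sided). Within 5 classes of equal size by H3K27ac reads per kb the odds ratio fell from 7.74 in the lowest class to 2.82 in the highest. Peak width was not matched, and a wider peak has more room to overlap p300 and c-Jun alike. The c-Jun signal had a median of 4.13 times the input over 6168 peaks with enough reads, and 6096 of them were above input by limma-voom. The highest fold was on chromosome 17 from 64148181 to 64148859, with 9.27 ± 2.19 CPM for c-Jun and 0.390 ± 0.378 for input (SD, n = 2; log2 fold change 4.81, SE 0.86, limma adjusted p = 0.000233). The peaks were called on these libraries, so the count describes them and is no independent test. It was 0 without input replicate 1 and 0 without input replicate 2 in limma-voom, where 1026 and 170 peaks had an unadjusted p below 0.05, and 11130 without c-Jun replicate 1.

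Around the centres of the c-Jun peaks, H3K27ac dipped between a pair of flanking maxima. The central 200 bp had 0.835 ± 0.066 times the signal of the highest 100 bp bin 200 to 600 bp away in myoblasts and 0.887 ± 0.011 times in myotubes (SD, n = 2 each). Against the mean of all bins at that distance the ratios were 0.928 ± 0.092 and 0.992 ± 0.013, so that the dip is one relative to the maxima. p300 was highest at the centre, with 2.59 ± 0.36 times the reads found 2.5 to 3 kb away in myoblasts and 1.99 ± 0.06 times in myotubes (SD, n = 3 each). The c-Jun libraries had 6.71 ± 1.13 times and the input libraries 1.31 ± 0.06 times the distant level (SD, n = 2 each). These profiles were added after the data had been seen and were not tested between states.

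**Figure D3:**
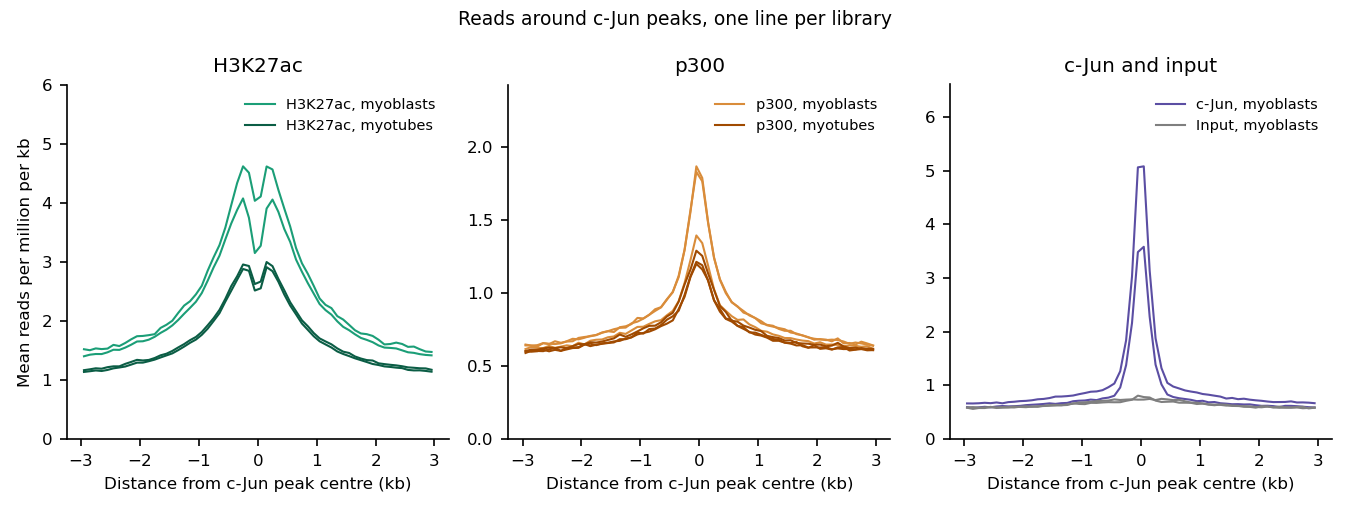
Mean CPM per kb against the distance from the centre of c-Jun peaks in kb, for H3K27ac (left), p300 (middle) and c-Jun with input (right), 1 line per library. The H3K27ac centre had 0.835 times the signal of the highest flanking bin and 0.928 times the mean of the flanking bins in myoblasts, and p300 peaked at the centre at 2.59 times the distant level in myoblasts and 1.99 times in myotubes.

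Regions bound by c-Jun in myoblasts were compared with other regions for their change on differentiation. The 7148 p300 regions with a c-Jun peak had a median p300 log2 fold change of -0.32, against 0.09 for the others, and 8.52% of them fell against 0.59% of the others. The shares depended on single libraries: 16.6% against 1.24% fell without myoblast replicate 1. Without myotube replicate 1 they were 4.24% against 0.17%, and without myotube replicate 2 3.97% against 0.13%. Of the 761 p300 regions that fell, 80.03% had a c-Jun peak, compared with 7.81% of the 743 that rose and 20.7% of those not called. The regions with c-Jun were lower than the others in each of 5 classes of p300 signal, with medians of -0.56 against 0.09 in the lowest class and of -0.29 against 0.05 in the highest. Within the myoblast list alone, added after the data had been seen, the medians were -0.45 and -0.22. The set differed from other p300 regions by camera (adjusted p = 3.95e-16 over the 2 sets, preset correlation 0.01; adjusted p = 0.0114 with an estimated correlation). The difference of the medians was -0.41 with all libraries and -0.36 without myotube replicate 3, the library with no reads on unplaced contigs. With the estimated correlation the call was lost when 10 kb bins or total reads set the scaling (adjusted p = 0.184 and 0.0822; range over 8 alternatives that used all libraries 0.0119 to 0.184).

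For H3K27ac the 17290 regions with a c-Jun peak had a median log2 fold change of -0.43, against 0.13 for the others, and 24.1% of them fell against 7.32% of the others. The difference of the medians was -0.55 with all libraries. It was -0.65 and -0.42 without myoblast replicates 1 and 2, and -0.33 and -0.42 without myotube replicates 1 and 2. In 5 classes of H3K27ac signal, from the lowest to the highest, the medians with and without c-Jun were 0.74 and 1.20, -0.04 and 0.05, -0.06 and 0.04, -0.26 and 0.01, and -0.57 and -0.38. Among regions without c-Jun matched for mean signal, 20.3% fell on average over 100 draws, against 24.1% of those with c-Jun. This matching was chosen after the data had been seen. Of the H3K27ac regions that fell, 21.8% had a c-Jun peak, compared with 4.59% of those that rose. These shares rest on H3K27ac calls, whose number depended strongly on single libraries. The camera test gave an adjusted p of 4.88e-07 with the preset and of 0.0114 with an estimated correlation. Within the myoblast list alone the medians were -0.50 with and -0.51 without c-Jun, a difference of 0.01 whose sign is opposite to that of the test, although 25.3% against 11.1% fell. The call ended there with the preset correlation (adjusted p = 0.164), and also with cyclic loess normalization (adjusted p = 0.0830), where the difference was -0.16. With an estimated correlation the adjusted p was 0.05 or above in 3 of 8 alternatives that used all libraries (range 0.00192 to 0.439). In each of the 4 fits with a library left out, the estimated correlation gave a camera p of 0.05 or above before adjustment.

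**Figure D4:**
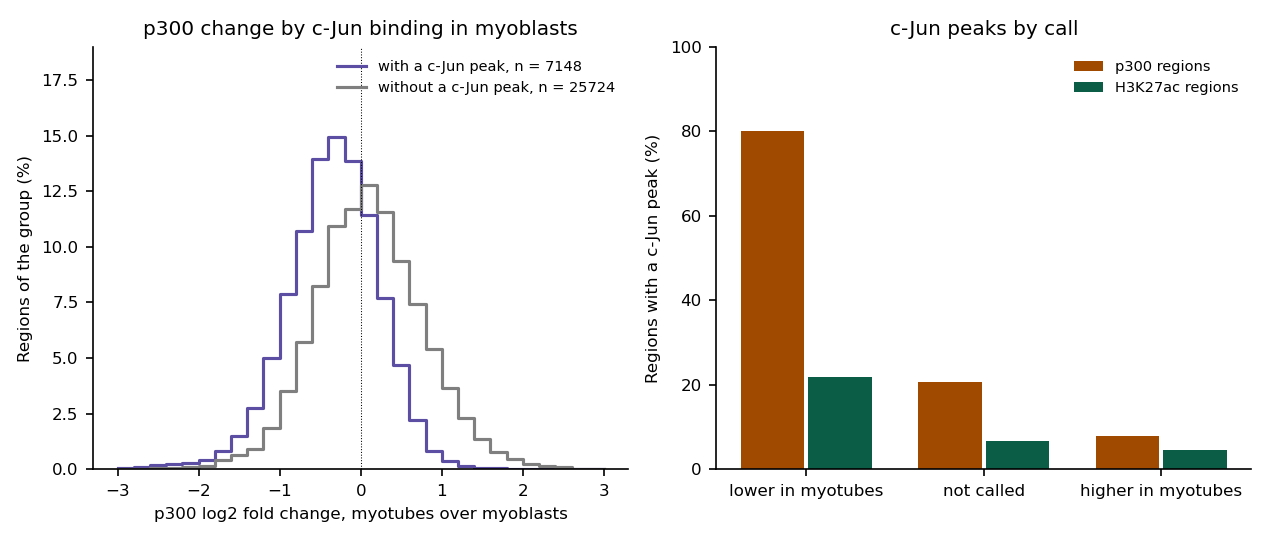
Left, distribution of the p300 log2 fold change (myotubes over myoblasts) in percent of regions, for p300 regions with (7148) and without a c-Jun peak. Right, percent of p300 and H3K27ac regions with a c-Jun peak by call: 80.03% of lower and 7.81% of higher p300 regions, 21.8% of lower and 4.59% of higher H3K27ac regions. The number of H3K27ac calls depended strongly on single libraries.

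The changes of p300 and H3K27ac were set against each other at p300 regions, since the libraries of the antibodies share no sample. Where p300 rose, H3K27ac counted within 500 bp of the region centre had a median log2 fold change of 1.27 and was higher in 83.5% of 739 regions. Where p300 fell, the median was -0.71 and H3K27ac was lower in 72.3% of 758 regions. Where p300 was not called, the median was -0.28 and H3K27ac was higher in 41.3%, so that most of these regions were lower too. H3K27ac was itself called higher at 292 regions with a p300 gain and lower at 6, and called lower at 173 regions with a p300 loss and higher at 2. Across 28420 regions, which are not independent replicates, Pearson's r was 0.319 and Spearman's rho 0.266 (permutation p = 0.001 for each, the smallest that 1000 permutations can give; the same after adjustment over the 2 correlations). Over classes of p300 change without regard to the call, the median H3K27ac change was 1.78 in the class with the largest p300 gains, while it was -0.53 in the class at a p300 median of -0.23 and -0.19 in the class with the largest losses.

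**Figure D5:**
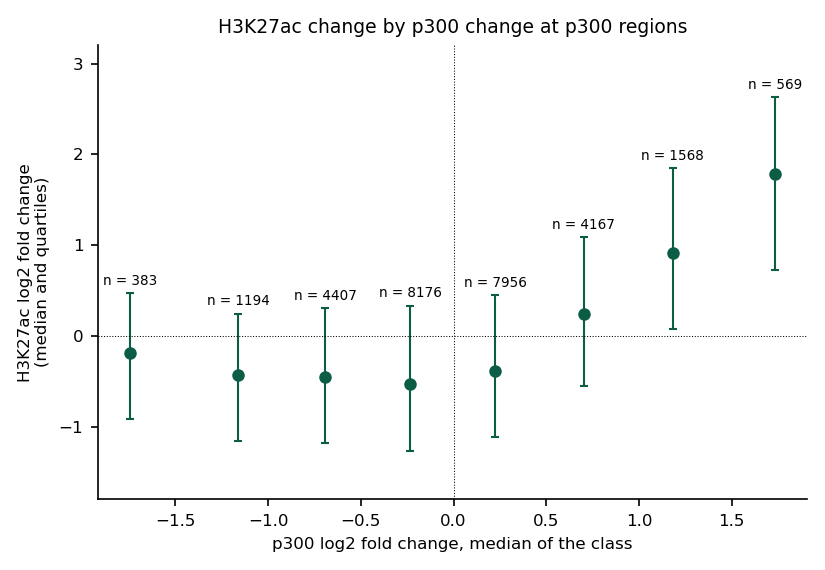
Median H3K27ac log2 fold change with quartiles against the median p300 log2 fold change, for classes of p300 regions by p300 change, with the number of regions beside each point. H3K27ac reached 1.78 where p300 gained most and stayed between -0.53 and -0.19 in the 4 classes of p300 loss.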

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

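The comparisons of mitochondrial reads, the share of p300 reads in peaks of H3K27ac and c-Jun and the H3K27ac ratio were all chosen after the reads outside the main chromosomes had been seen. Reads outside chromosomes 1 to 19 and X exceeded the input libraries in several groups. On unplaced contigs lay 0.0855% of the reads of H3K27ac in myoblasts, 0.0619% in myotubes and 0.101% of p300 in myoblasts, against 0 in input. Reads on chromosome Y were 4.77 per 1000000 reads for p300 in myoblasts and 5.15 in myotubes, against 2.96 and 3.32 in the input libraries. The c-Jun and input files held 0 reads on contigs and on the mitochondrial genome alike, so their 0 is not a measured level.

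Mitochondrial reads made up 0.0267% ± 0.0069 of the p300 libraries in myoblasts and 0.0775% ± 0.0122 in myotubes (SD, n = 3 each), every myotube library being above every myoblast one (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). Without myotube replicate 3 the myotube mean was 0.0841%. A weaker enrichment of the myotube libraries stays open. The share of p300 reads in c-Jun peaks went from 1.59% ± 0.22 in myoblasts to 1.22% ± 0.05 in myotubes, a ratio of 0.769 (0.7499 without myotube replicate 3), but in H3K27ac peaks of myoblasts and of myotubes the ratios were 1.01 and 1.09 (0.947 and 1.04 without that replicate), and binding itself may differ between the states. More mitochondrial DNA in myotube chromatin may contribute. The H3K27ac libraries held 0.000159% in myoblasts and 0.000666% in myotubes, a ratio of 4.18 (n = 2 each, exact permutation p = 0.333, the smallest possible), on too few samples to decide, and no myotube input was analysed here.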

How the results depend on the processing

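Cyclic loess, counting without the shift, the restrictions to particular lists, no filter on c-Jun peaks, overlaps within 500 bp, domains and the other scalings of the c-Jun sets were chosen after the data had been seen, as was the upper part of the c-Jun list by width. For H3K27ac, 11728 regions changed when only regions in both lists were fitted, against 5583 higher and 14033 lower calls at these regions in the fit to all; their median moved from -0.22 to 0.12. The other scalings, filters and windows stayed within 1.5 times of 35624. The range over libraries left out was 6189 to 146655 regions, and 916 to 14482 domains. For p300, 969 regions changed with 10 kb bins, 926 with no filter, 27 within 250 bp of the centre (5757 tested) and 319 in both lists (10721 tested), and 767 to 2306 with a library left out. Above input were 10865 c-Jun peaks with no filter (18708 tested), and 0 to 11130 with a library left out (without either input library, 1026 and 170 had an unadjusted p below 0.05). The causes were not tested. The p300 difference at c-Jun peaks kept its direction and its side of the threshold with the preset correlation in all 15 other settings, from -0.54 to -0.23. The H3K27ac difference did so in all but 2 of 12, and was 0.0061 in the myoblast list alone and -0.16 with cyclic loess, the cause not tested.

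For p300 the replicate numbers gave no sign of pairing by correlation. Deviations of same-numbered p300 libraries correlated at -0.027, 0.0054 and -0.018, and not every p300 library correlated best with its own number. For H3K27ac the value was 0.0845. With 2 libraries per state the other-numbered value is fixed at its negative, so pairing cannot be judged there. With the replicate block 52331 H3K27ac regions, 8564 domains, 2222 p300 regions and 6105 c-Jun peaks were called, against 35624, 4986, 1504 and 6096 without it. The block changed no call of the c-Jun sets.

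An overlap of 0.5 of the shorter peak, the upper 0.5 of each list by width, and a distance within 500 bp gave 57.2%, 62.1% and 72.9% of myoblast H3K27ac peaks shared with myotubes, and 45.1%, 49.1% and 61.7% of myotube peaks shared with myoblasts. For p300 they gave 11.7%, 13.4% and 20.2% of myoblast peaks and 13.1%, 14.99% and 22.6% of myotube peaks. For p300 on H3K27ac they gave 18.6%, 22.3% and 24.99% in myoblasts and 33.4%, 37.5% and 42.5% in myotubes. For c-Jun on p300 they gave 35.7%, 42.0% and 44.3%, and for c-Jun on H3K27ac 64.9%, 77.6% and 82.3%. The overlap of 0.5 is stricter and the distance looser by construction, and for the split by width the cause was not tested. The odds ratio of c-Jun at H3K27ac peaks with p300 was 6.18, 6.12 and 4.31 under them. With H3K27ac counted within 1000 bp of the p300 region centre, r of the p300 and H3K27ac changes was 0.327.

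Of the named H3K27ac regions, 28 of 40 values with a library left out and all 90 under other settings kept their call, and of the named p300 regions 54 of 60 and 79 of 89; none reversed. Alternatives on promoters, gene lists, motifs, distance from transcription start sites and pseudocounts were not run, removal of duplicates would remove 0 reads, and lists were split by width, since no authors' score was used here. The count model planned as the main test was not run. Of another count model, planned as an alternative, only the median-ratio size factors were used, in voom. Of 205920 p300 regions, 32872 held enough reads to be tested.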

Other observations

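The tests of p300 signal at regions of 1 list alone and of p300 loss by the amount of c-Jun were fixed before their results were seen, and the other tests and descriptions here were chosen after. Neighbouring H3K27ac changes went the same way: of 19273 pairs of adjacent changed regions up to 12.5 kb apart, 93.2% had the same direction, against 50.3% if directions were independent. Of 4284 adjacent pairs over 100 kb apart, 56.4% did. Chromosome X held 2074 H3K27ac peaks in myoblasts and 3617 in myotubes, and its regions had a median log2 fold change of 0.52 against 0.07 elsewhere, but it did not pass as a set (camera in limma, adjusted p = 0.756, and adjusted p = 0.761 with an estimated correlation). At 76.3% of c-Jun peaks an H3K27ac peak was listed in myotubes, and at 30.2% a p300 peak, against 10.7% and 5.84% at random and 16.7% and 8.40% on input reads.

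p300 lists shared few peaks between states. If peaks of 1 list alone were background, the p300 libraries of the other state would lie at the level of input there. Relative to input and to bins without peaks they were 1.15 ± 0.0057 times as high in myoblasts at peaks of myotubes alone and 1.21 ± 0.089 times in myotubes at peaks of myoblasts alone (SD, n = 3 each), between the bounds set beforehand, so the share of background peaks cannot be told apart from weak binding in both states. The libraries of the same state reached 1.77 and 1.96 times there, but the peaks were called on them. The median H3K27ac change differed by 0.018 between peaks of myotubes alone (0.08, SD 1.16 over 54972 regions) and of myoblasts alone (0.07, SD 1.08 over 40260). The SDs are spreads over regions and not errors of the medians. These values argue against state-specific p300 binding with a matching H3K27ac change at most of these peaks. H3K27ac is not a measure of p300 binding itself, so that state-specific binding without such a change stays open.

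Regions with a c-Jun peak were lower in myotubes than other regions. When they were compared with regions of the same signal level over 100 draws, differences of -0.14 for H3K27ac (SD over draws 0.011) and -0.40 for p300 (SD 0.0078) remained, against -0.55 and -0.41 before. The p300 value argues against signal level as the whole cause. The H3K27ac value lies between the bounds set, so that for H3K27ac signal level stays open. Most of the H3K27ac difference was gone after this matching. Of the H3K27ac regions with c-Jun 24.1% fell, against 20.3% of the matched ones, and 4.39% against 11.3% rose. Matching for list membership too gave -0.071 for H3K27ac (SD 0.0089), which decides nothing, since the lists were called on the same libraries. For p300 a difference of -0.25 (SD 0.0064) remained even so, 8.52% against 3.15% fell and 0.81% against 4.02% rose. This argues against mean signal and list membership as the whole cause. The SDs cover the draws only. Matching used the mean signal over both states, not the myoblast signal, and c-Jun was mapped in myoblasts alone. A selection of regions more active in myoblasts therefore stays open. A hypothesis drawn from the matched p300 comparison is that p300 is lost where c-Jun was bound in myoblasts, and more so with more c-Jun. Its test was whether, among p300 regions with a c-Jun peak, the highest of 3 equal groups by c-Jun over input lost more p300 than the lowest in 5 classes of p300 signal. The mean difference of the medians was 0.13, opposite in sign to this prediction, from 0.065 to 0.205 over the classes and from 0.122 to 0.146 in log2 CPM with a p300 library left out. However, c-Jun was counted over the whole p300 region, and region width was not matched. p300 regions that fell were wider (median 1933 bp, against 1120 bp where not called), which may dilute their c-Jun over input. The value therefore does not decide whether the loss grows with the amount of c-Jun. A loss at any level of c-Jun, or through a factor bound with it, stays open too, and c-Jun in myotubes was not analysed here.

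The 6 p300 libraries form 10 splits of 3 against 3, and 1 split, that by state, gave as many as 1504 changed regions. The highest of the other splits gave 0 (limma-voom; 357 to 1443 regions had an unadjusted p below 0.05, against 6660 for the split by state). With 10 splits no share under 0.05 can be reached.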
